A study of Mus musculus with 2 samples.

How the data were processed

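RNA from primary mouse keratinocytes was hybridised to 1-colour (Cy3) Agilent expression arrays, 1 array for the Rac3-KO sample and 1 for the sample labelled Rac1/Rac3-DKO; the groups come from the genotype labels. Total RNA was extracted with a column kit and amplified to labelled cRNA, per the labels' protocols. The deposited scanner files hold spot intensity, read at 3 microns per pixel and extracted with Feature Extraction 10.10.1.1, per the file headers; the submitters' processing notes name Agilent Feature Extraction 9.1. The file headers give fits of a spatial and a multiplicative detrending within each array, and the processed signal was not scaled between arrays. Both arrays lay on the same slide and share the same scan, per the file headers, so slide and scan do not separate the groups. The authors' deposited value table is on a log2 scale. Set against the scanner files, it equals the log2 processed signal minus a constant for each array, close to that array's 75th percentile, for 100% of the probes spotted a single time, within a tolerance of 0.001; its column medians are -3.72 for Rac3-KO and -3.62 for the DKO-labelled array. Its scale and centring are thereby known, and as a 1-colour level it has no direction to settle.

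Log2 processed signals were averaged over the spots of a probe, leaving out control spots and spots that the software marked as outliers, 155 and 190 on the Rac3-KO and DKO-labelled arrays. This removed 3 probes and left 55678. Each array's 75th percentile over these probes was subtracted. Probe accessions were matched, without versions, to RefSeq transcripts of the GRCm38.p6 gene table, used for names only because the array design refers to an earlier build; 26580 probes received the name of 1 of 20144 genes and 29098 stayed unnamed here. A gene was represented by its probe with the highest mean level. Of 3578 genes with several probes well above background, 285 had probes whose log2 differences lay at least 1 apart and 4 had probes at least 2-fold apart in opposite directions. A gene was called measured when that probe was well above background on both arrays. A gene was called detected on a single array when it had a probe well above background there and none on the other array. It then received an at-least fold, the bright level against the higher of the dim probe's own level and the lowest level well above background on the dim array.

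With 1 array per genotype no test between genotypes was run, and counts used a threshold of 2-fold. The error given is technical only: the SD over repeated spots (268 probes spotted at least 8 times), the SD between probes of a gene (root mean square 0.38) and the software's own signal error (median 0.20 on the log2 difference). None of them holds variation between cultures or animals. Before the data were examined, 43 gene lists and markers of other cell types were fixed from textbook knowledge, together with families by symbol that needed at least 8 measured members. The Lce and Sprr families fell below that number. The results of 1 list and of some list members are not reported here. Each list was summarised by its median log2 difference and by the percentile of that median among 10000 random lists of the same size matched on mean level, which describes these 2 arrays and is not a test.

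The genes named in the text were also chosen by rules fixed before the data were examined. They are Rac1 and Rac3; the 10 genes with the largest difference in each direction among genes well above background and not saturated on both arrays, where the difference exceeded 1.96 times the software's signal error, leaving out clone, model and accession names; the 3 with the largest at-least fold in each direction; and, for each list, up to 2 members each way among those at least 2-fold apart or with an at-least fold of 2 or more, or the largest each way where there were none, with the 2 brightest members of marker lists. Further members named to complete a small count or to give a member that goes against its list were chosen after their values were seen: these are Rac2, Rhog, Myh4, Krt5, Col17a1, Trp63, Itgb1, Krt2, Tgm3, Cdh1, Mcm3, Mcm4, Krt71, Tchh, Sox9, Gli2, Ptch1, Nrarp, Gdf15, Vegfa, Vegfd, Lif, Fgf21, Fgf20, Igfbp5, Wnt6, Abca12, Cyp4f39, Serpinb12 and Serpinb7, and the sex-linked genes Uty, Kdm5d and Xist.

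Alternatives recomputed were normexp background correction, other scalings between the arrays (median, 75th percentile over probes detected on both arrays, quantile, loess on the mean level and spike-ins), no filter and a stricter filter on dim probes, the mean over a gene's probes, saturated spots left out, the deposited value table, fold thresholds of 1.5 and 3, the software's error as a filter, unmatched random lists and the mean of a list. Leaving out the genes of the marker lists, and the members that a list shares with a marker list, was added after the data were seen. The mean spot signal was not used here; normexp with an offset of 50 was run on the median spot signal. After a change of scaling, list medians and genes were centred on the median of the measured genes again. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used. The counting and list steps were tested on simulated data made from the 14145 measured genes of this comparison, with a noise SD of 0.27. Of 50 genes changed by 1.5 (log2) 96% were recovered upward and of 50 changed by -1.5 94% downward, and at 2.5 and -2.5 100%. Of 13945 unchanged genes 104 came out at least 2-fold apart, and 6.5% of 200 unchanged lists fell outside the central 95%. The noise was set from the spread between probes of a gene and drawn independently for each gene, and the simulated lists were random genes. The measured log2 differences had an SD of 0.74, so these shares hold for the simulated setting and are not error rates for the 2 arrays.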

Results

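Gene expression was measured in primary keratinocytes, the epithelial cells of the epidermis, from mice labelled as lacking Rac3 and from mice labelled as lacking both Rac1 and Rac3. Rac1 and Rac3 are small GTPases, which relay signals to the actin cytoskeleton. The labels describe the cells as P3 primary keratinocytes and name the Rac3-KO sample as the control. The series title places the comparison in the question of how Rac in keratinocytes affects fat cells of the dermis, so genes of secreted signals were among the gene lists examined. Each genotype was represented by 1 array, so there were no replicates, no difference had a replicate check, and no test between genotypes was possible. On the Rac3-KO array 31704 of 55678 probes (56.9%) were well above background, and on the array labelled Rac1/Rac3-DKO 29434 (52.9%). The 75th percentile of the processed signal before scaling was 705 on the Rac3-KO array and 354 on the DKO-labelled array. The lowest signal well above background was 23.4 and 20.1, respectively, and no spot was saturated. The number of arrays limits the precision of every value. Genes known from other tissues had high processed signals on the Rac3-KO and DKO-labelled arrays alike: 435050 and 361120 for the haemoglobin gene Hba-a1, 393720 and 357520 for the fibroblast collagen gene Col1a2, 97854 and 259870 for the muscle gene Tnnc2, and 72955 and 47797 for the adipocyte gene Fabp4. Both samples thus held RNA of tissues other than keratinocytes, and a difference of a keratinocyte gene also depends on the share of keratinocyte RNA in each sample.

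Rac1, the gene that distinguishes the groups in the labels, was not lower on the DKO-labelled array. Its brighter probe had a log2 level of 4.82 on the Rac3-KO array and 5.10 on the DKO-labelled array, relative to each array's 75th percentile, a difference of 0.28 with a signal error of 0.20 from the scanner software. A further Rac1 probe differed by -0.12. The Rac1 probes therefore do not bear out the label, but they do not contradict it either. Both samples held RNA of other tissues, and which cells gave the Rac1 signal was not measured. The labels do not give the deleted exon and the probes were not placed on the transcript here, so the probes may lie outside the deleted part, in which case they check nothing. Rac3, deleted in both groups per the labels, was nevertheless well above background on both arrays, with processed signals of 99.8 and 59.1, so its probe does not bear out the label of either group, or lies outside the deleted part. It differed by 0.24 with a signal error of 0.24 and checks nothing between the groups. The related GTPases Rac2 and Rhog differed by 0.64 and 0.66.

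Keratinocyte genes were lower and striated muscle genes higher on the DKO-labelled array than on the Rac3-KO array. Krt1 and Krt10, the keratin pair of differentiating epidermal cells, were 31.0-fold and 22.6-fold lower, and the basal keratins Krt15 and Krt14 were 4.95-fold and 3.79-fold lower. Ckm, the creatine kinase of muscle, was 8.02-fold higher, and Tnni2, a troponin of fast skeletal muscle, 6.32-fold higher. Of 14145 genes well above background on both arrays, 1091 (7.71%) were at least 2-fold higher on the DKO-labelled array and 937 (6.62%) at least 2-fold lower. A further 230 genes were well above background on the DKO-labelled array only and 858 on the Rac3-KO array only, or 53 and 431 when the brighter signal had to exceed 2 times the lowest signal well above background. With an at-least fold of 2 or more, which takes the different floors of the scaled arrays into account, the counts were 183 and 188. Log2 levels correlated across measured genes with r = 0.958; genes are not independent replicates. Higher genes made up 53.8% of those at least 2-fold apart, and 43.6% when each array was scaled to its median instead of its 75th percentile. Spike-in RNAs differed by 1.06 (log2) and the 75th percentile by -0.99 before scaling, so that on the spike-in scale 14 genes were at least 2-fold higher and 13167 at least 2-fold lower, and all differences below are relative to each array's 75th percentile. The technical spread within these 2 arrays was small beside the largest differences. The log2 difference of repeated spots of a probe had a median SD of 0.09. Between different probes of a gene the median SD was 0.19 and the root mean square 0.38. Background correction moved several large differences by more than this, as given below.

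**Figure D1:**
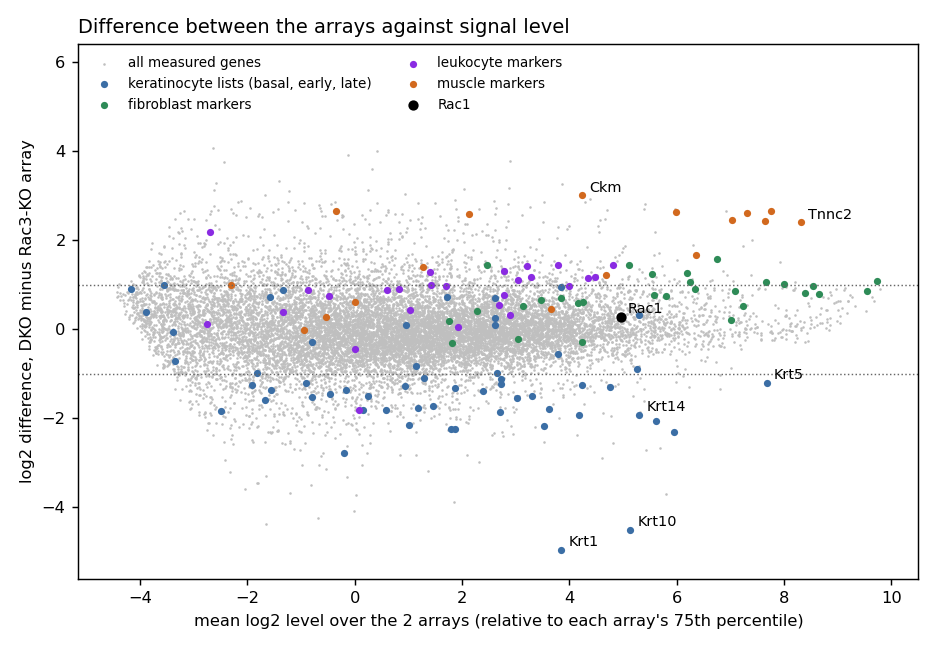
Each point is a gene well above background on both arrays; the x axis is its mean log2 level relative to each array's 75th percentile and the y axis its log2 difference, DKO-labelled minus Rac3-KO array, with dotted lines at 2-fold. Muscle markers (orange) have a median of 2.40 and lie above the line of no difference except Myh4 at -0.02, members of the 3 keratinocyte lists (blue) lie mostly below it down to -4.95 for Krt1, and Rac1 (black) lies at 0.28.

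**Figure D2:**
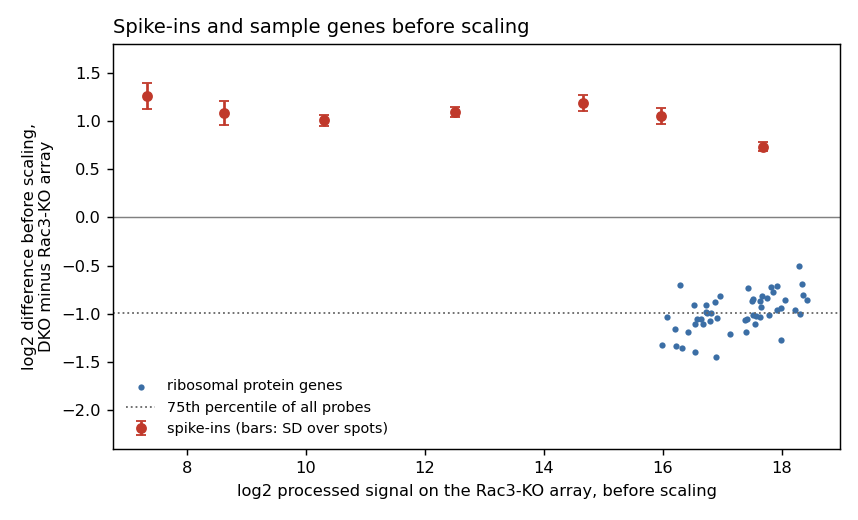
Each red point is a spike-in RNA with all spots well above background on both arrays, with its log2 difference before scaling, DKO-labelled minus Rac3-KO array, against its log2 signal on the Rac3-KO array; bars show the SD over spots. The 7 spike-ins lie between 0.74 and 1.26, while the 75th percentile of all probes (dotted line) lies at -0.99 with the ribosomal protein genes (blue) around it.

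None of the 10 genes with the highest differences belongs to the fixed muscle list, but several, such as Trim63, Mstn, Tcap and Csrp3, are muscle genes too. They are therefore not separate from the muscle pattern. Myl2, a regulatory myosin light chain, was 16.8-fold higher on the DKO-labelled array, the muscle ubiquitin ligase Trim63 15.9-fold, Ankrd2 15.0-fold and the actin-filament regulator Lmod2 13.5-fold. The small heat shock protein Hspb7 was 12.2-fold higher, Dusp13 9.96-fold, the muscle growth inhibitor Mstn 9.73-fold, and the sarcomere Z-disc proteins Tcap and Csrp3 9.63-fold and 8.93-fold. Stxbp4, a syntaxin-binding protein, was 13.6-fold higher at its brightest probe, while the mean over its probes gave a log2 difference of 1.18 in place of 3.77. With normexp background correction several of these log2 differences were smaller: 2.5003 in place of 4.07 for Myl2, 3.31 in place of 3.91 for Ankrd2, 2.42 in place of 3.75 for Lmod2, 2.52 in place of 3.32 for Dusp13 (2.64 with the mean over its probes) and 2.005 in place of 3.28 for Mstn. Among genes well above background on the DKO-labelled array only, Lrtm1 was at least 12.4-fold, Faim2 at least 10.3-fold and Spint5 at least 6.72-fold higher.

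The genes with the lowest differences included several of epidermis and its barrier. After Krt1 and Krt10, the cytochrome P450 gene Cyp2b10 was 20.7-fold lower on the DKO-labelled array and the protease inhibitor gene Serpinb3c 18.8-fold lower. The threonine dehydrogenase gene Tdh was 16.8-fold lower, the transmembrane protease gene Tmprss4 14.7-fold, and the epidermal ceramidase gene Acer1 13.3-fold. Stfa3, a cysteine protease inhibitor, was 13.0-fold lower, the proton pump subunit gene Atp6v1b1 12.7-fold and the deacetylase gene Aadac 11.9-fold. With normexp the log2 differences were -2.89 in place of -4.37 for Cyp2b10, -3.16 in place of -4.23 for Serpinb3c, -3.30 in place of -4.07 for Tdh, -3.14 in place of -3.73 for Acer1, -2.68 in place of -3.67 for Atp6v1b1 and -1.72 in place of -3.57 for Aadac, while Krt1 and Krt10 gave -4.94 and -4.66. Among genes well above background on the Rac3-KO array only, the Y-linked genes Eif2s3y and Ddx3y were at least 62.5-fold and at least 24.6-fold lower on the DKO-labelled array, and Serpinb3a at least 35.7-fold. The samples thus differed in Y-linked RNA as well as in the genotype label. Genes of the Stfa, Serpinb3, Gsta, Sprr, Lce and haemoglobin families have near-identical copies, and a probe may read more than a single copy.

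Keratinocyte genes of the basal layer, of early differentiation and of the cornified envelope were lower together. Of 19 measured basal keratinocyte genes, 12 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 difference of -1.31, at percentile 0 of 10000 random lists matched on level. Col17a1, a hemidesmosome collagen, was 3.60-fold lower, Trp63, the transcription factor of stratified epithelia, 3.48-fold, and Krt5 2.30-fold, while Itgb1 was 1.63-fold higher. Of 18 early differentiation genes 12 were at least 2-fold lower (median -1.55, percentile 0), among them Krt1 and Krt10; Krt2 was 1.66-fold higher. Of 20 cornified envelope and late differentiation genes 13 were at least 2-fold lower (median -1.25, percentile 0), led by the protease genes Klk5 at 6.89-fold and Asprv1 at 4.73-fold, whereas Lce3c, well above background on the DKO-labelled array only, was at least 2.52-fold higher and Tgm3 was 1.64-fold higher. With no filter on detection the late list lost its call, with a median of -0.012 over 41 genes at percentile 24.4. The members that this adds were not well above background on both arrays, so the loss rests on signals that include the floor. On the same arrays the markers of muscle and fibroblasts had medians of 2.40 and 0.79.

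Other keratinocyte groups were mixed. Of 19 epidermal barrier lipid genes 7 were at least 2-fold lower and 1 higher, with a median of 0.10 (percentile 80.7) but a mean of -0.59. Acer1 and the fatty acid elongase gene Elovl4 were 13.3-fold and 7.10-fold lower, and the sphingomyelinase gene Smpd3 2.57-fold higher. Abca12 and Cyp4f39, well above background on the Rac3-KO array only and so not among the 19, were at least 3.75-fold and 4.45-fold lower. No member of the list was detected on the DKO-labelled array only. Of 13 activated keratinocyte genes 4 were at least 2-fold lower and 1 higher (median -0.45, percentile 0.70), a call lost with the mean over a gene's probes at percentile 17.0. Stfa3 and Stfa1 were 13.0-fold and 6.56-fold lower, and Lcn2, an iron-binding antimicrobial protein, was 3.02-fold higher beside leukocyte markers with a median of 0.93.

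Cell junction genes, cholesterol synthesis genes and proliferation genes were lower as groups. Of 36 cell junction genes 20 were at least 2-fold lower and 1 at least 2-fold higher (median -1.03, percentile 0). Tjp3, a tight junction scaffold, differed by -2.32 (log2), and the desmosomal cadherin Dsg1a was 4.44-fold lower and E-cadherin, Cdh1, 3.16-fold lower, while the endothelial claudin Cldn5 was 2.10-fold higher beside endothelial markers with a median of 0.59. Of 25 cholesterol synthesis genes 14 were at least 2-fold lower and 0 higher (median -1.17, percentile 0), with Idi1 at 3.94-fold and Lss at 3.69-fold. All 47 measured proliferation genes had a difference below 0, and 12 were at least 2-fold lower (median -0.71, percentile 0). The chromatin factor genes Hells and Uhrf1 differed by -1.40 and -1.32 (log2), and the replication helicase genes Mcm3 and Mcm4 were 2.49-fold and 2.48-fold lower. Muscle and fibroblast markers were higher by medians of 2.40 and 0.79 beside these groups.

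**Figure D3:**
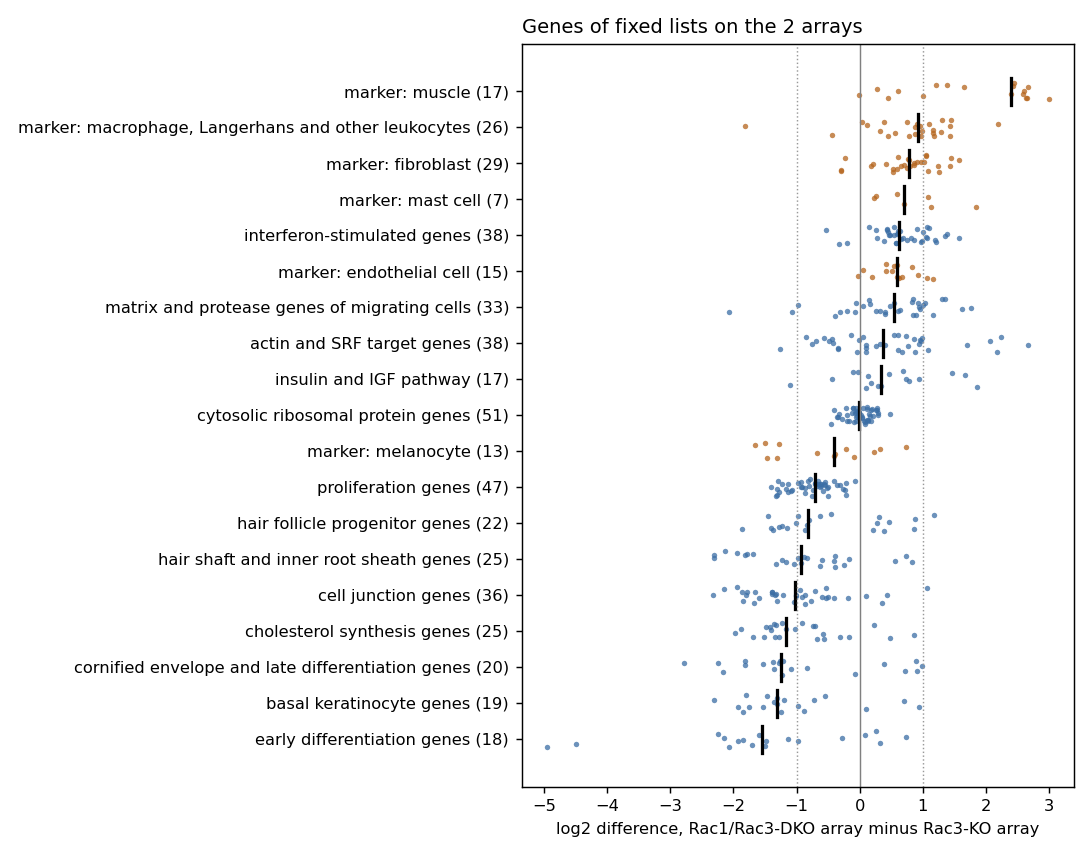
Each point is the log2 difference, DKO-labelled minus Rac3-KO array, of a gene well above background on both arrays, with a row per list, the number of genes in brackets and a black bar at the list's median; marker lists of other cell types are orange and dotted lines mark 2-fold. Medians run from -1.55 for early differentiation genes to 2.40 for muscle markers, with ribosomal protein genes close to 0.

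Hair follicle genes were lower too. Of 25 hair shaft and inner root sheath genes 11 were at least 2-fold lower and 0 higher (median -0.93, percentile 0). The inner root sheath keratin gene Krt71 was 3.84-fold lower and the sheath protein Tchh 4.94-fold, and Krt34 and Krt72, well above background on the Rac3-KO array only, were at least 5.41-fold and 5.28-fold lower. Of 22 hair follicle progenitor genes 8 were at least 2-fold lower (median -0.82, percentile 0), among them Plet1 at 3.65-fold and Sox9 at 2.66-fold. Edar, the ectodysplasin receptor, was at least 6.35-fold lower, while Ccn2 was 2.27-fold higher. Among 13 Hedgehog pathway genes 4 were at least 2-fold lower and 0 higher (median -0.46, percentile 0.48), among them Shh at 3.93-fold, Gli2 at 2.30-fold and Ptch1 at 2.17-fold. With the mean over a gene's probes the Hedgehog median was -0.14 at percentile 21.6. Of 21 Notch pathway genes 3 were at least 2-fold lower, namely Hes5 at 5.96-fold, Jag2 at 2.38-fold and Nrarp at 2.14-fold (median -0.39, percentile 0.58), and with background correction by normexp the median was -0.14 at percentile 18.8; the mean of the list, -0.28, lay at percentile 3.14. Of 13 melanocyte markers 5 were at least 2-fold lower and 0 higher, and the list, with a median of -0.40 at percentile 3.95, did not stand apart. Muscle, fibroblast and leukocyte markers were higher on the same arrays by medians of 2.40, 0.79 and 0.93.

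Genes of secreted signals, the group closest to the series title, went in both directions. Among 17 ligands of the BMP and TGF-beta family, 2 were at least 2-fold lower, Bmp2 at 2.62-fold and Gdf15 with a log2 difference of -1.002, and 0 were at least 2-fold higher (median -0.08, percentile 37.2). Bmp5 was well above background on the Rac3-KO array only and at least 3.61-fold lower on the DKO-labelled array. Among 19 BMP antagonists and BMP target genes, the antagonist gene Sostdc1 was 3.07-fold lower and Grem1 and Fstl1 were 3.02-fold and 2.08-fold higher (median -0.17, percentile 18.0). Among 29 other secreted growth factors, 3 were at least 2-fold lower, namely Pthlh at 3.26-fold, Pdgfa at 3.05-fold and Vegfa at 2.42-fold. The 3 at least 2-fold higher were Fgf2 at 2.42-fold, Csf1 at 2.11-fold and Vegfd at 1.002 (log2) (median 0.26, percentile 97.0). Lif and Fgf21, well above background on the Rac3-KO array only, were at least 2.72-fold and at least 2.47-fold lower, and Fgf20, detected likewise, at least 1.07-fold. Fibroblast and leukocyte markers, whose cells also make growth factors, had medians of 0.79 and 0.93.

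The insulin and IGF pathway was the only fixed list of secreted signals to stand above the central 95% of matched random lists. Of its 17 measured genes 3 were at least 2-fold higher and 1 lower (median 0.34, percentile 98.9), a call lost against random lists not matched on level at percentile 97.0. Igf2, a growth factor of fetal tissue and muscle, was 3.61-fold higher, the binding protein genes Igfbp6 and Igfbp5 3.18-fold and 2.76-fold higher, and Igfbp2 2.14-fold lower. Muscle markers were higher by a median of 2.40 beside them. Among 14 Wnt ligands 5 were at least 2-fold lower and 2 higher (median -0.35, percentile 7.65). Wnt3 was 6.42-fold and Wnt6 3.48-fold lower, Wnt7a, well above background on the Rac3-KO array only, at least 6.14-fold lower, and Wnt2 and Wnt2b 2.72-fold and 2.33-fold higher. Among 25 Wnt target genes and antagonists 5 were at least 2-fold lower and 1 higher (median -0.28, percentile 3.17), with Dkkl1 at 3.71-fold and Rnf43 at 3.37-fold lower and Sfrp4 3.12-fold higher. Of 8 EGF receptor ligands and receptors only Epgn was at least 2-fold apart, 2.42-fold lower (median 0.13, percentile 66.5). Among 24 cytokines and chemokines 5 were at least 2-fold lower and 0 higher (median 0.13, percentile 77.5), led by the interleukin family member Il1f5 at 5.45-fold and Cxcl14 at 2.34-fold, while Ccl17, well above background on the DKO-labelled array only, was at least 2.39-fold higher.

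Markers of most other skin cell types were higher on the DKO-labelled array, and those of muscle by the most. Of 17 muscle markers 12 were at least 2-fold higher and 0 lower (median 2.40, percentile 100). The bright muscle gene Tnnc2 was 5.28-fold higher, while Myh4 differed by -0.02. Of 26 markers of macrophages, Langerhans cells and other leukocytes 10 were at least 2-fold higher and 1 lower (median 0.93, percentile 100), with Cd163 at 4.56-fold, Csf1r at 2.72-fold and Itgam at 2.24-fold higher and Epcam 3.50-fold lower. Of 29 fibroblast markers 9 were at least 2-fold higher (median 0.79, percentile 100), with Mfap5 at 2.97-fold, Fbln2 at 2.72-fold, Sparc at 2.11-fold and Col1a2 at 1.81-fold. Of 7 mast cell markers 3 were at least 2-fold higher (median 0.70, percentile 99.4), namely Fcer1a at 3.59-fold, Mcpt4 at 2.20-fold and Hdc at 2.11-fold; the bright marker Cpa3 was 1.19-fold higher, and with no filter on detection the median of 0.45 no longer stood apart. Of 15 endothelial markers 2 were at least 2-fold higher, Kdr at 2.25-fold and Cldn5 at 2.10-fold, with Egfl7 at 1.34-fold (median 0.59, percentile 99.96).

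Of 15 adipocyte markers, 1 was at least 2-fold higher, the hormone gene Retn at 2.22-fold, and 1 at least 2-fold lower, Pck1 at 3.56-fold (median 0.57, percentile 99.8), a call lost with the mean of the list, 0.35. The bright adipocyte genes Fabp4, a fatty acid carrier, and Car3, a carbonic anhydrase, were 1.30-fold and 1.59-fold higher. Of 4 erythroid markers Slc4a1 was 4.09-fold higher (median 0.71, percentile 95.2); Hba-a1 and Alas2 were 1.65-fold and 1.62-fold higher. Among melanocyte markers Slc45a2 was 3.17-fold, Dct 2.83-fold and Pmel 1.60-fold lower. Of 8 Schwann cell markers only Pmp22, 2.29-fold higher, was at least 2-fold apart, with Gap43 at 1.86-fold higher (median 0.19, percentile 86.7). Of 7 markers of Merkel cells and simple epithelium Isl1 was 2.14-fold higher, Krt7 2.20-fold lower and Piezo2 1.07-fold higher (median 0.10, percentile 57.5).

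Interferon-stimulated genes, matrix genes and actin genes were higher as groups, in the same direction as leukocyte, fibroblast and muscle markers with medians of 0.93, 0.79 and 2.40. Of 38 interferon-stimulated genes 10 were at least 2-fold higher and 0 lower (median 0.63, percentile 100), with the chemokine Cxcl9 at 2.97-fold and the antiviral enzyme Rsad2 at 2.60-fold. Of 33 matrix and protease genes of migrating cells 7 were at least 2-fold higher and 2 lower (median 0.54, percentile 99.99). Tnc, a matrix protein of remodelling tissue, and the metalloprotease inhibitor gene Timp1 were 3.40-fold and 3.07-fold higher, and the epithelial integrin subunit Itgb6 (log2 difference -2.07) and the proteoglycan Sdc1 (2.11-fold) lower. Of 38 actin and SRF target genes 6 were at least 2-fold higher and 1 lower (median 0.37, percentile 99.9). Tropomyosin gene Tpm1 was 6.33-fold and Pdlim5 4.71-fold higher, both also muscle genes, and Egr2 was 2.39-fold lower. Among 18 YAP target genes 4 were at least 2-fold higher and 1 lower (median 0.24, percentile 92.6), with Ankrd1 at 4.17-fold and Axl at 2.62-fold higher and Ajuba 2.58-fold lower.

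Genes that act downstream of Rac did not stand apart as a group. Among 26 genes of Rac effectors and NADPH oxidase Noxa1 was 2.30-fold lower and 3 were at least 2-fold higher (median 0.02, percentile 47.9), led by the oxidase subunits Ncf1 at 3.87-fold and Nox1 at 2.94-fold. Ncf1 is a gene of phagocytes, and leukocyte markers were higher by a median of 0.93.

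Stress and metabolism lists held large differences of single genes in both directions. Among 34 antioxidant and NRF2 target genes 8 were at least 2-fold higher and 2 lower (median 0.12, percentile 76.0). Hmox1, which degrades haem, was 6.96-fold and the metallothionein gene Mt1 4.01-fold higher, while the glutathione transferase genes Gsta2 and Gsta1 were 11.2-fold and 8.22-fold lower. Among 31 hypoxia and glycolysis genes 2 were at least 2-fold higher and 5 lower (median 0.03, percentile 52.4): the glucose transporter gene Slc2a1 was 5.28-fold and Pfkl 4.83-fold lower, and Bnip3 3.32-fold and the muscle aldolase gene Aldoa 2.83-fold higher. Among 25 genes of ER stress and the amino acid response 5 were at least 2-fold lower and 3 higher (median -0.25, percentile 1.85), with Atf3 at 5.82-fold and Sdf2l1 at 2.89-fold lower and Vldlr and Chac1 at 2.87-fold and 2.70-fold higher; this call was lost against unmatched random lists at percentile 3.72. Among 27 p53 target and senescence genes Sfn was 3.73-fold lower and Pmaip1 differed by -1.78 (log2), and Trp53inp1 and Sesn1 3.47-fold and 2.70-fold higher (median -0.18, percentile 9.65). Among 25 sebocyte and fatty acid synthesis genes 4 were at least 2-fold lower and 3 higher (median -0.0049, percentile 41.6), with Elovl3 at 4.63-fold and Elovl6 at 3.30-fold lower and Scd1 at 2.88-fold and Thrsp at 2.18-fold higher. All 51 cytosolic ribosomal protein genes lay within 2-fold (median -0.0041, percentile 0.30 against lists matched on level and 51.2 against unmatched lists), from Rpl22 at 1.37-fold lower to Rplp0 at 1.40-fold higher. Of 19 control genes only Tfrc, the transferrin receptor, was at least 2-fold apart, 3.41-fold lower (median 0.04, percentile 35.5).

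Gene families defined by symbol repeated part of this picture. The keratin family had 17 of 36 genes at least 2-fold lower and 1 higher, Krt222 at 2.47-fold (median -0.90, percentile 0), and the histone family 6 of 53 lower and 1 higher (median -0.32, percentile 0), with H2bu2 at 4.07-fold lower and H3c15 at 2.32-fold higher. The Rpl and Rps families had medians of -0.0027 and -0.0092 at percentiles 0.77 and 1.76, and 51.6 and 49.1 against unmatched lists; the muscle paralogue Rpl3l was 6.39-fold higher. Families above the central 95% were the Ccl chemokines (4 of 14 higher, 1 lower, median 0.48, percentile 99.5), with Ccl6 at 3.87-fold and Ccl9 at 3.39-fold higher and the epidermal chemokine gene Ccl27a 2.22-fold lower beside leukocyte markers with a median of 0.93, the Cyp family (3 of 36 higher, 2 lower, median 0.49, percentile 99.9), with Cyp1b1 3.53-fold higher, Cyp2b10 20.7-fold lower and Cyp4x1, well above background on the Rac3-KO array only, at least 5.18-fold lower, and the S100a family (0 of 12 higher, 2 lower, median 0.45, percentile 98.4), in which S100a14 was 3.68-fold lower. The calls of the Cyp and S100a families were lost with the mean of the list, at percentiles 86.3 and 66.5. The kallikrein family split: Klk11 and Klk5 were 8.22-fold and 6.89-fold lower and Klk1b26 and Klk1b16 6.57-fold and 6.41-fold higher (median 0.40, percentile 95.04). Families within the central 95% were Krtap (median 0.06, percentile 59.3), Serpinb (0.23, 83.1), Mmp (0.49, 95.3), Cxcl (-0.37, 6.10), Gst (-0.02, 45.6), Slc7a (-0.49, 2.75), Aldh (-0.17, 20.7), Ndufa and Ndufb (0.17, 78.4), Psma and Psmb (-0.06, 20.4) and Col (0.30, 95.9). These medians cover measured genes only. Serpinb12 and Serpinb7, well above background on the Rac3-KO array only, were at least 18.2-fold and 7.51-fold lower. No Serpinb gene was detected on the DKO-labelled array only.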

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

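The test of the spike-in shift by the range of the spike-ins was chosen after the results were seen, as was the look at ribosomal protein genes; the spike-in scale itself was planned. Signals that the report's comparison does not use differed between the arrays. Of 16194 probes that carry genomic regions in place of a gene name, 4673 were well above background on both arrays; 594 (12.7%) of these were at least 2-fold higher on the DKO-labelled array and 150 (3.21%) at least 2-fold lower, with a median log2 difference of 0.33. Among named probes 7.55% were at least 2-fold higher and 6.21% lower. Region and named probes were not matched on signal level. Among named genes the stricter filter on dim probes lowered only the higher count, from 1091 to 953, with 937 lower in both cases. Low signal alone may thus add to the share of higher probes. In mm9 coordinates of the array design the lowest value was -4.05, for chromosome 12 from 85196395 to 85262884, and the highest 3.45, for chromosome 3 from 148884650 to 148888709. No explanation was tested for these probes.

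The spike-in RNAs, added in known amounts and not part of the sample, had a mean log2 difference of 1.06 before scaling (SD 0.17 over 7 spike-ins), while the 75th percentile of all probes differed by -0.99. On the spike-in scale the 75th percentile was thus 4.15-fold lower on the DKO-labelled array, and the cytosolic ribosomal protein genes had a median of -2.06 (from -2.51 to -1.57), which follows from a constant shift and decides nothing about its cause. A non-linear response of the spike-ins is argued against by their range of 0.53, which is less than the shift of -2.05 over spike-ins of very different brightness. Less labelled sample RNA, or more spike-in mix, on the DKO-labelled array may explain the shift. Neither was measured, and both stay open; the labels give the same RNA input for both samples. A shift common to all genes leaves the differences between genes as reported.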

How the results depend on the processing

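All alternatives were chosen before the data were examined, except leaving out members that 7 lists share with a marker list, which changed no call, and leaving out the marker genes, which gave 1051 higher and 929 lower genes of 14006. The latter kept muscle genes outside the marker lists, such as Trim63 and Mstn, so it does not measure what other tissues add to these counts. Rac1 differed by 0.08 to 0.28. The 20 genes with the largest differences kept their direction in all 80 recomputed values that could change, but 15 of the 80 moved by more than the spread between probes, 13 of them with normexp, down to -1.72 for Aadac and 2.005 for Mstn; the smallest size was 1.18, for Stxbp4 with the mean over probes. Of 30 lists and families outside the central 95% of random lists, 17 stayed on the same side under every alternative, and of 31 inside, 19 stayed inside; no list standing apart reversed. Of 495 recomputations of a list that could change its value, 451 kept its side, 22 lost and 22 gained a call; constant scalings, leaving out saturated spots, which removed none, and the deposited value table, the same signal minus a constant, are not counted. The causes were not tested.

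Scaling by a constant leaves list medians as they are once centred again. On the spike-in scale, with a shift of -2.05, 14 genes were higher and 13167 lower. Against 1091 higher and 937 lower genes in the main counts, normexp gave fewer, 768 and 664 of 14140. Quantile normalization gave 993 and 994 and loess 931 and 1055, so the direction with more genes depended on the scaling. No filter gave 2122 and 1521 genes over 20144, the 1.5-fold threshold 2581 and 2335, and the 3-fold threshold 324 and 315. With the brighter signal above 2 times the lowest well above background, 53 genes were detected on the DKO-labelled and 431 on the Rac3-KO array only; with an at-least fold of 2 or more there were 183 and 188.

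Calls lost, by list median: with normexp, activated keratinocyte -0.27, Notch -0.14 and ER stress -0.24; with no filter, cornified envelope -0.012, activated keratinocyte -0.23, mast cell 0.45, S100a 0.20 and Cyp 0.45; with the stricter filter, ER stress -0.22 and Cyp 0.23; with the mean over probes, activated keratinocyte -0.16, Hedgehog -0.14 and ER stress -0.23. With the mean of a list they were Notch -0.28, adipocyte 0.35, S100a 0.14 and Cyp 0.17. Against unmatched lists they were IGF 0.34, ER stress -0.25, ribosomal protein -0.0041, Rpl -0.0027 and Rps -0.0092. The values with no filter include members that were not well above background on both arrays.

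Calls gained: with normexp, BMP antagonists and targets -0.36, Wnt targets -0.35, Klk 0.54 and Col 0.36; with quantile normalization, other growth factors 0.30 and Slc7a -0.51; with loess, p53 targets -0.28, Slc7a -0.54 and Col 0.27; with no filter, melanocyte -0.69, Krtap -0.30 and Slc7a -0.48. With the mean over probes they were other growth factors 0.26 and melanocyte -0.52. With the mean of a list they were barrier lipid -0.59, Wnt ligands -0.51, Wnt targets -0.35, melanocyte -0.59 and Serpinb -0.48. Against unmatched lists they were melanocyte -0.40, Slc7a -0.49 and Col 0.30. Some lists moved far without changing their call. Other growth factors went from percentile 97.0 to 75.2 with normexp, 77.8 with the stricter filter and 35.3 with no filter. Cytokines and chemokines went from 77.5 to 8.77 with the stricter filter. The lower signal on the DKO-labelled array, 354 against 705 at the 75th percentile, limits the detection of dim genes there.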

Other observations

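The tests of the muscle and keratinocyte patterns in this part were chosen after the results were seen, though the loess scaling that 2 of them use was planned. Further gene families held large differences of single members. Among keratin-associated protein genes of the hair shaft, 13 were well above background on the Rac3-KO array only; Krtap6-1, among these, was at least 7.96-fold lower on the DKO-labelled array and Krtap8-1 5.96-fold lower, while Krtap19-4 and Krtap31-1 were 2.68-fold and 2.13-fold higher. Of 33 measured collagen genes 5 were at least 2-fold lower, led by the basement membrane chain Col4a6 at 4.37-fold and Col9a1 at 4.30-fold, and 3 at least 2-fold higher, led by Col5a3 at 2.43-fold and Col6a6 at 2.39-fold beside fibroblast markers with a median of 0.79. Ndufa4l2 was 4.09-fold lower, the only one of 24 Ndufa and Ndufb genes at least 2-fold apart. The aldehyde dehydrogenase gene Aldh3b2 was 4.60-fold lower and Aldh1a1, which makes retinoic acid, 2.45-fold higher. The amino acid transporter gene Slc7a8 was 2.91-fold higher and Slc7a3 2.31-fold lower. All 17 measured Psma and Psmb proteasome genes lay within 2-fold.

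Sex-linked genes differed in detection. The Y-linked genes Eif2s3y and Ddx3y had processed signals of 2498 and 984 on the Rac3-KO array and 4.33 and 4.64 on the DKO-labelled array, and 2 probes of Uty were well above background on the Rac3-KO array only. Kdm5d was well above background on neither array. Xist was well above background on both arrays, with log2 differences of 0.81 and 1.01 at its 2 probes. The labels give no sex. The Rac3-KO array thus showed Y-linked RNA and Xist together, so the groups cannot be read as a male against a female sample. Whether cells of several animals were pooled was not known here. The detected Y-linked genes separate the 2 arrays in the same way as the genotype labels. With 1 array per group, an effect of sex cannot be told apart from an effect of the genotype.

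Striated muscle genes were higher on the DKO-labelled array. Of 14 measured striated members of the muscle list, 85.7% were at least 2-fold higher. A smaller share of keratinocytes that raises every other cell type alike is argued against, since the striated muscle median lay 1.65 (log2) above the fibroblast median (95% interval over resampled genes 0.65 to 1.92). That interval holds the spread between genes on these 2 arrays, not the variation between samples. A trend of the difference with signal level is argued against by a muscle median of 2.27 after loess. A larger amount of skeletal muscle tissue in the DKO-labelled sample may explain the pattern, and an effect of the genotype on the cells stays open with 1 array per group.

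Keratinocyte genes were lower on the DKO-labelled array, and after loess the basal list kept a median of -1.31, which argues against a trend with signal level. An even dilution of keratinocyte RNA by other tissue would lower every keratinocyte gene alike, and it cannot be told apart here from a change of the cells. Of 57 measured members of the 3 keratinocyte lists, 2 (Krt1 and Krt10) lay below Krt5 by more than 2.11, which is 2 SDs of a difference between 2 genes from the spread of all measured genes, against 1.27 by chance and a bound of 3.82. That spread includes the muscle and keratinocyte differences themselves, so this form could hardly decide. It counted only members below Krt5, while the 57 members ranged from -4.95 to 0.99. This test was changed 3 times after values were seen. The first form, the share of members close to the common median, gave 59.6% with 64.3% for striated muscle; later forms that used only the noise between probes, which holds no variation between samples, gave 9 against 1.30 and 4 against 1.27. With 1 array per group, how much of the pattern a dilution accounts for was not measured. An even dilution alone would have given Krt1 and Krt10 the difference of Krt5, -1.20, yet they lay at -4.95 and -4.50. These are the lowest of the 57 members, so they do not speak for the others.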
